A study of Mus musculus with 7 samples.

How the data were processed

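Mononuclear cells were isolated from the tibialis anterior of male C57BL/6 mice by collagenase and dispase digestion, sorted with a viability stain, and processed with the 10x Genomics 3′ v3 chemistry, per the labels. Each of the 7 libraries pooled 3 mice. Per the submitters' processing notes, reads were processed with Cell Ranger and Seurat against mm10. The versions, the annotation and the cell filters are not given in the sources used here. The values of the deposited matrix are the natural log of 1 plus a corrected count, made by the authors with the SCT normalization named in the series description. This unit was checked on the values: all 124388270 nonzero values became whole numbers after the log was undone, within a relative tolerance of 1e-06, and the totals per cell ranged from 5509 to 9930. The matrix held 18658 genes and 53193 cells, and 12.5% of its entries were above 0. Corrected counts are not molecules observed, so no count model and no interval on a gene value was used.

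The design assumed counts that could be summed. Because the matrix holds corrected counts, the log was undone and means per cell of each class were compared, scaled so that all genes sum to 1000000 (CPM). Cells with at least 200 genes detected and at most 20% mitochondrial counts were to be kept, which removed 0 cells. Values were scaled to 10000 per cell and logged. The 2000 most variable genes, 30 principal components and 20 neighbours were used for Leiden clustering at resolution 1.0, with all libraries together and no batch integration, which gave 36 clusters. Of these, 3 were clustered again, which gave 51 groups. The cell classes, their markers (16 classes), the 26 gene lists, the thresholds and the rule for naming genes were chosen before the data were examined.

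A cluster took the class with the highest mean scaled value of its markers among classes with at least 3 markers detected in 20% of its cells. It was left unnamed if its median doublet score was over 0.8, if its 10 leading genes held more markers of another class, or if its cells were shallow and no marker was among those genes. These limits on unnamed clusters were set after seeing the data, and they left 1564 cells (2.94%) unnamed. A cell was called shallow when the median nonzero corrected count of its low genes was 2 or more. No doublets were removed in the main values; an alternative removed the cells with the highest scores, at 0.8% per 1000 cells of the library. Doublet scores came from simulated doublets among nearest neighbours.

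With 1 library per time point no test between time points was run. Each injured library was compared with non-injured muscle within a class of at least 50 cells in both, and with 21 dpi for endothelial-like cells. Genes at 50 CPM or more in either library were considered, 10 CPM was added to both values, and genes over 2-fold higher or lower were counted as a description. The named genes are the 4 highest and 3 lowest log2 ratios among genes at 100 CPM or more in either library, without mitochondrial, ribosomal protein and haemoglobin genes or unnamed gene models. To these are added 2 to 4 members of each described list with the largest absolute log2 ratios, and the fixed markers. List members at 10 CPM or more in either library were measured, and the list median was ranked among 10000 random lists of the same size matched in 20 expression bins. Where the median of all measured genes was over 0.1 from 0, list medians are given relative to it. For the proliferation share each cell was thinned to 2000 counts. Shares of cells have exact Clopper-Pearson 95% intervals, and a share of 0 has the limit that 3 cells would give. Gene positions come from the GENCODE vM21 annotation on GRCm38, the build also called mm10, in which 71 of the 72 genes named by the rule on log2 ratios had 1 location.

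The comparison was tested on simulated data made from these libraries. Apart from the changed genes, both groups of a pair were drawn from the mean profile of the reference class with counting noise only. Differences between libraries or mice were not simulated, so the rates below do not cover them. With 200 genes changed 3-fold, 96.5% were over 2-fold for monocyte/macrophage-like cells at 0.5 dpi, 99.5% for FAP-like cells at 5 dpi, 97.0% for myogenic progenitor-like cells at 3.5 dpi and 94.5% for endothelial-like cells at 10 dpi. With no gene changed, the numbers over 2-fold were 0, 0, 0 and 2. Of 200 unchanged lists in each comparison, 4.0%, 5.0%, 5.0% and 6.0% lay outside percentiles 2.5 to 97.5, and a list of 12 genes doubled lay at percentile 100 in each. The unchanged lists were drawn at random from the genes that also gave the random lists, with independent noise for each gene. Rates near 5.0% were therefore set by the design, and they do not cover lists whose members vary together.

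Alternatives tried were a stricter cell filter (500 genes and 10% mitochondrial counts, which removed 1195 cells), no cell filter, doublet removal, Leiden resolutions 0.5 and 2.0, a class per cell from marker scores, an added value of 1 CPM, a minimum of 10 CPM, the mean over cells of values CPM, thinning to 1000 and a minimum of 3 counts for proliferation. Removing shallow cells, putting unnamed clusters in their best class and median-ratio scaling were added after seeing the data. Scaling factors that need counts were not run. List medians and gene ratios were not recomputed at the other Leiden resolutions, so their ranges over the alternatives do not cover these. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.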

Results

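Single-cell RNA sequencing measured gene expression in mononuclear cells of the mouse tibialis anterior muscle, before injury and while it regenerated. The injury was made with cardiotoxin, a snake venom toxin that lyses myofibres and leaves the basement membrane and the resident stem cells in place. The 7 libraries covered non-injured muscle and muscle taken 0.5, 2, 3.5, 5, 10 and 21 days post injury (dpi). Each library pooled the cells of 3 male C57BL/6 mice aged 3 months, so every time point rested on 1 library and no difference between time points has a replicate check. The table held 5670 cells from non-injured muscle, 3510 at 0.5 dpi, 8395 at 2 dpi, 11251 at 3.5 dpi, 9491 at 5 dpi, 6214 at 10 dpi and 8662 at 21 dpi. The authors' correction brought every cell to between 5509 and 9930 corrected counts, so the sequencing depth of a cell cannot be read from these values. The median number of genes detected per cell was 2728 in non-injured muscle, 2228.5 at 0.5 dpi, 2429 at 2 dpi, 2178 at 3.5 dpi, 2476 at 5 dpi, 2594 at 10 dpi and 2058 at 21 dpi. Gene values below are mean corrected counts per cell of a class, scaled so that all genes sum to 1000000 (CPM), and log2 ratios were taken after adding 10 CPM to both values. Each list median was ranked among 10000 random lists matched on expression, and its percentile was 100 or 0 after rounding to 3 digits unless another is given.

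The first comparison asks which cells occupied the muscle before and after injury. In non-injured muscle most cells were fibro-adipogenic progenitor (FAP)-like, the stromal cells that produce matrix and can form fat, or myocyte-like. At 0.5 dpi most cells were monocyte/macrophage-like or neutrophil-like, the phagocytes that clear debris. Myogenic progenitor-like cells, the class that holds the muscle stem cells, had their highest share of all cells at 5 dpi. At 21 dpi FAP-like cells again made up most of the library.

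FAP-like cells made up 61.6% of the non-injured library (3490 cells, exact Clopper-Pearson 95% interval 60.3 to 62.8%). Their share was 9.60% at 0.5 dpi (337 cells, 8.65 to 10.6%), 5.43% at 2 dpi, 11.6% at 3.5 dpi, 22.4% at 5 dpi, 37.4% at 10 dpi and 63.8% at 21 dpi (5529 cells, 62.8 to 64.8%). Because the shares of a library sum to 100%, the FAP-like share was also taken among named cells outside the immune classes. There it was 68.2% in non-injured muscle, 93.9% at 0.5 dpi and 78.7% at 21 dpi. Unnamed cells, 111 of them at 0.5 dpi, were left out, and counting them would lower these shares. Monocyte/macrophage-like cells made up 2.28% of non-injured muscle (129 cells, 1.90 to 2.70%). Their share was 45.9% at 0.5 dpi, 60.8% at 2 dpi and 67.9% at 3.5 dpi (7642 cells, 67.1 to 68.8%), followed by 54.1% at 5 dpi, 37.9% at 10 dpi and 10.5% at 21 dpi. Neutrophil-like cells made up 1.98% of non-injured muscle, 34.6% at 0.5 dpi (1214 cells, 33.0 to 36.2%), 23.5% at 2 dpi and 0.675% at 3.5 dpi (76 cells). The share at 0.5 dpi was 14.7% without the cells called shallow here, in which genes of low mean value had a median nonzero corrected count of 2 or more. Dendritic-like cells, which present antigen to T cells, made up 1.06% of non-injured muscle and 11.4% at 3.5 dpi (1285 cells, 10.84 to 12.02%). The share of dendritic-like cells in non-injured muscle was 1.75% at Leiden resolution 0.5 and 1.72% under the stricter cell filter. The intervals here and below cover counting error only.

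Myogenic progenitor-like cells made up 2.93% of non-injured muscle (166 cells, 2.504 to 3.40%). Their share was 0.228% at 0.5 dpi (8 cells), 0.274% at 2 dpi (23 cells), 2.99% at 3.5 dpi, 4.49% at 5 dpi (426 cells, 4.08 to 4.92%), 3.64% at 10 dpi and 1.63% at 21 dpi. These are shares of all cells, and at 3.5 dpi 7642 of the 11251 cells were monocyte/macrophage-like. Set beside FAP-like cells, progenitor-like cells numbered 166 to 3490 in non-injured muscle, 336 to 1306 at 3.5 dpi and 426 to 2127 at 5 dpi. The time of the highest share thus depends on which cells are counted. The share of myogenic progenitor-like cells at 21 dpi was 2.82% at Leiden resolution 0.5 and 1.04% at resolution 2.0, so the size of its difference from non-injured muscle depends on the clustering. Myocyte-like cells made up 22.3% of non-injured muscle (1263 cells, 21.2 to 23.4%), 0.142% at 0.5 dpi (5 cells), 1.09% at 5 dpi (103 cells) and 3.71% at 21 dpi (321 cells). In non-injured muscle their median mitochondrial share was 0.212% of counts, against 4.82% in progenitor-like cells. Whether these droplets held whole cells was not tested. At resolution 0.5 the cluster led by Myog was named myogenic progenitor, and 1 myocyte-like cell was left at 5 dpi. Endothelial-like cells, which line blood vessels, made up 0.758% of non-injured muscle (43 cells) and 3.57% at 21 dpi (309 cells, 3.19 to 3.98%). Mural-like cells, which wrap small vessels, made up 0.247% of non-injured muscle (14 cells) and 2.89% at 21 dpi (250 cells). Tenocyte-like cells, the fibroblasts of tendon, made up 2.35% of non-injured muscle and 5.26% at 21 dpi (456 cells). None was found among the 3510 cells at 0.5 dpi, which allows a share of up to 0.0855%. Unnamed clusters held between 2.01% of cells (non-injured muscle) and 4.04% (21 dpi). With 1 library per group, a cluster drawn mostly from 1 library may be that library and not a type.

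**Figure D1:**
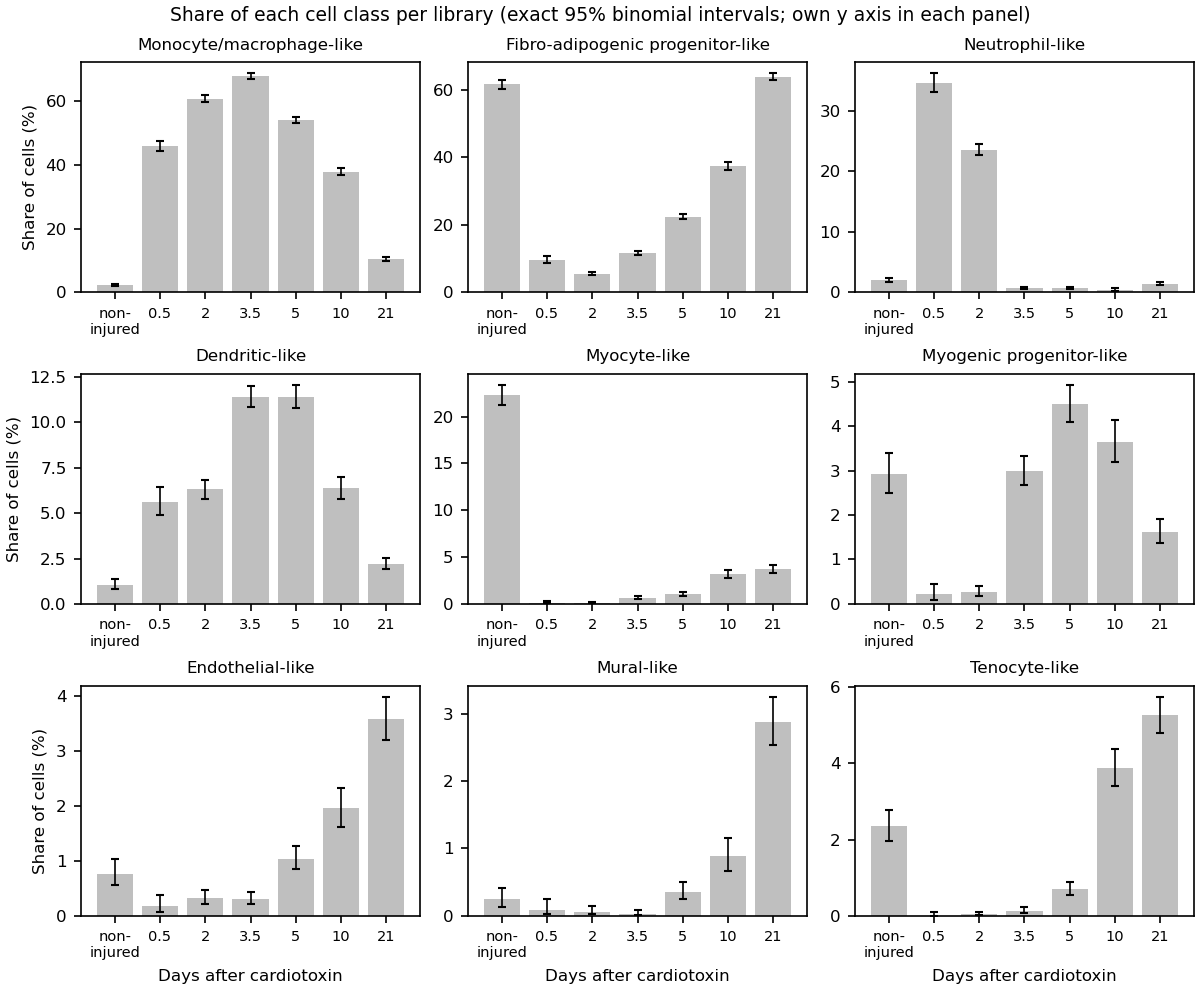
Share of each of 9 cell classes among all cells of a library (y axis, percent, own scale in each panel) by days after cardiotoxin (x axis), with exact 95% intervals. Monocyte/macrophage-like cells reach 67.9% at 3.5 dpi and neutrophil-like cells 34.6% at 0.5 dpi (14.7% without shallow cells), and FAP-like cells are lowest at 2 dpi (5.43%).

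The next comparison asks how macrophage gene expression differed through regeneration. At 0.5 dpi monocyte/macrophage-like cells had high values of neutrophil-attracting chemokines and low values of the class II genes that present antigen. From 2 dpi on, genes for lipid handling and phagocytosis were higher than in non-injured muscle. Interferon response genes had their highest list median at 3.5 dpi, and genes for secreted trophic factors were higher at 5 and 10 dpi. The non-injured reference held 129 cells, mainly in clusters 2, 29 and 13, whereas 93.5% of the class at 0.5 dpi lay in cluster 3 and 57.3% at 2 dpi in cluster 4. Cluster 2, led by Gdf15 and Il10, held 46 non-injured cells. The cluster led by these genes held 3 at resolution 2.0 and 3 under the stricter filter, where clusters led by Chil3 held 41 and 42.

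At 0.5 dpi, 591 genes were over 2-fold higher and 596 over 2-fold lower in monocyte/macrophage-like cells than in the non-injured class, among 3497 genes at 50 CPM or more in either. Of the 15 acute inflammatory cytokine genes measured, 14 were over 2-fold higher, with a median log2 ratio of 3.68. Cxcl3, a neutrophil chemokine on chromosome 5 (90786103 to 90789600, GRCm38), stood at 7574 against 5.91 CPM, a log2 ratio of 8.90. Ptgs2, the inducible prostaglandin synthase, stood at 4070.5 against 28.6, and Ccl7, a monocyte chemokine, at 2586 against 33.5. Arg1, which breaks down arginine, was at 922 and Inhba, the activin A subunit, at 705, and both were listed at 0 in the reference. Among 9 inflammatory monocyte genes, 2 of which were also markers of the class, 5 were over 2-fold higher and 2 over 2-fold lower, with a median of 2.29. Examples are Vcan, which encodes a matrix proteoglycan, at 2449 against 67.0, and Thbs1, encoding thrombospondin 1, at 11634 against 499.8. The glycolysis and hypoxia list had a median of 1.23, with 6 of 11 members over 2-fold higher, among them Vegfa (410.1 against 5.91), the vessel growth factor.

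Antigen presentation genes had a median of −3.08 at 0.5 dpi, with 8 of 9 over 2-fold lower and a median of −2.09 under the stricter cell filter. H2-Eb1, a class II beta chain on chromosome 17 (34305867 to 34316674), stood at 330.4 against 4706 CPM, and Cd74, the invariant chain, at 1754 against 15851. The resident macrophage list had a median of −2.39, with 5 of 8 members lower, including Lyve1 at 7.67 against 101.5. Retnla, a secreted protein of alternatively activated macrophages, had a log2 ratio of −8.64 (19.5 against 11800.2) and was detected in 41.9% of the non-injured class (54 of 129 cells, 33.2 to 50.9%). Cluster 29, with Retnla, Lyz1 and Mgl2 among its leading genes, held 40 of the 129 cells. No cluster was led by Retnla at resolution 0.5 or under the stricter filter, where the log2 ratio of Retnla was −6.81, and the dendritic-like cluster with Mgl2 among its leading genes held 79 and 76 non-injured cells in place of 38. In the same comparison the immediate early and dissociation list, whose members respond to tissue digestion, had a median of −2.70. The adult myofibre list, whose transcripts reach other cells as free RNA, had a median of −2.77, with Acta1 in the non-injured class at 2.85% of its whole-library value.

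At 2 dpi, 435 genes were over 2-fold higher and 358 lower in monocyte/macrophage-like cells (350 and 400 under median-ratio scaling). The lipid and phagocytosis list had a median of 2.76, with 11 of 13 measured members over 2-fold higher and 1 lower. Spp1, encoding osteopontin on chromosome 5 (104435118 to 104441050), stood at 10752 against 30.6 CPM, and Fabp5, a fatty acid binding protein, at 3155 against 81.8. Acute cytokine genes had a median of 1.99 and inflammatory monocyte genes 2.07. Antigen presentation genes had a median of −2.90, with alternatives from −4.21 to −1.81. Mgl2, a lectin of alternatively activated macrophages, stood at 1.21 against 621.1, and Lyz1, a lysozyme, at 20.4 against 1387, and these reference values also include cluster 29.

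At 3.5 dpi, 231 genes were over 2-fold higher and 282 lower (297 and 245 under median-ratio scaling), and the median of all measured genes was −0.11. The class lay mainly in clusters 5 (27.3%), 0 (25.5%) and 2 (20.3%), and cluster 5, led by genes such as Ifit3 and Rsad2, held 3 of the 129 non-injured cells. These values therefore include the shift between clusters. Interferon response genes had a median 1.98 above that of all genes, with 10 of 12 over 2-fold higher. Ifit3 stood at 234 against 17.7 CPM and Rsad2, an antiviral enzyme, at 326.3 against 63.1. The lipid and phagocytosis list lay 2.83 above all genes, with Gpnmb, a lysosomal glycoprotein, at 1194 against 7.89. The inflammatory monocyte list lay at −1.30 relative to all genes. Acute cytokine genes lay 0.35 above all genes, at percentile 95.1.

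At 5 dpi, 230 genes were over 2-fold higher and 256 lower (271 and 238 under median-ratio scaling). Cluster 0, which held 9 of the non-injured cells, held 32.7% of the class at 5 dpi and 41.9% at 10 dpi, and clusters 13 (25.8%) and 29 (21.9%) held the largest shares at 21 dpi. The trophic factor list had a median of 1.12, with 6 of 11 members over 2-fold higher, including Gdf15, a stress-induced member of the TGF-beta family, at 475.4 against 35.5 CPM, and Il10, an anti-inflammatory cytokine, at 143.0 against 7.89. Inflammatory monocyte genes had a median of −2.10, with Ccr2, the monocyte chemokine receptor, at 174.6 against 858.6. Lipid and phagocytosis genes had a median of 2.66. At 10 dpi, 217 genes were higher and 204 lower, or 284 and 161 under median-ratio scaling. Trophic factor genes had a median of 1.30, with Gdf15 at 768.0 and Igf1, a growth factor for muscle, at 320.9 against 105.5. Antigen presentation genes had a median of 0.27 at percentile 95.6, with H2-Aa at 7338 against 4743. H2-DMb2, which loads peptide onto class II, was the 1 member over 2-fold lower (9.54 against 57.2), and its log2 ratio was 0.074 under the stricter cell filter. The lipid and phagocytosis list had medians of 2.07 at 10 dpi and 1.28 at 21 dpi, when 132 genes were higher and 93 lower (166 and 75 under median-ratio scaling) and Spp1 stood at 826.0.

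**Figure D2:**
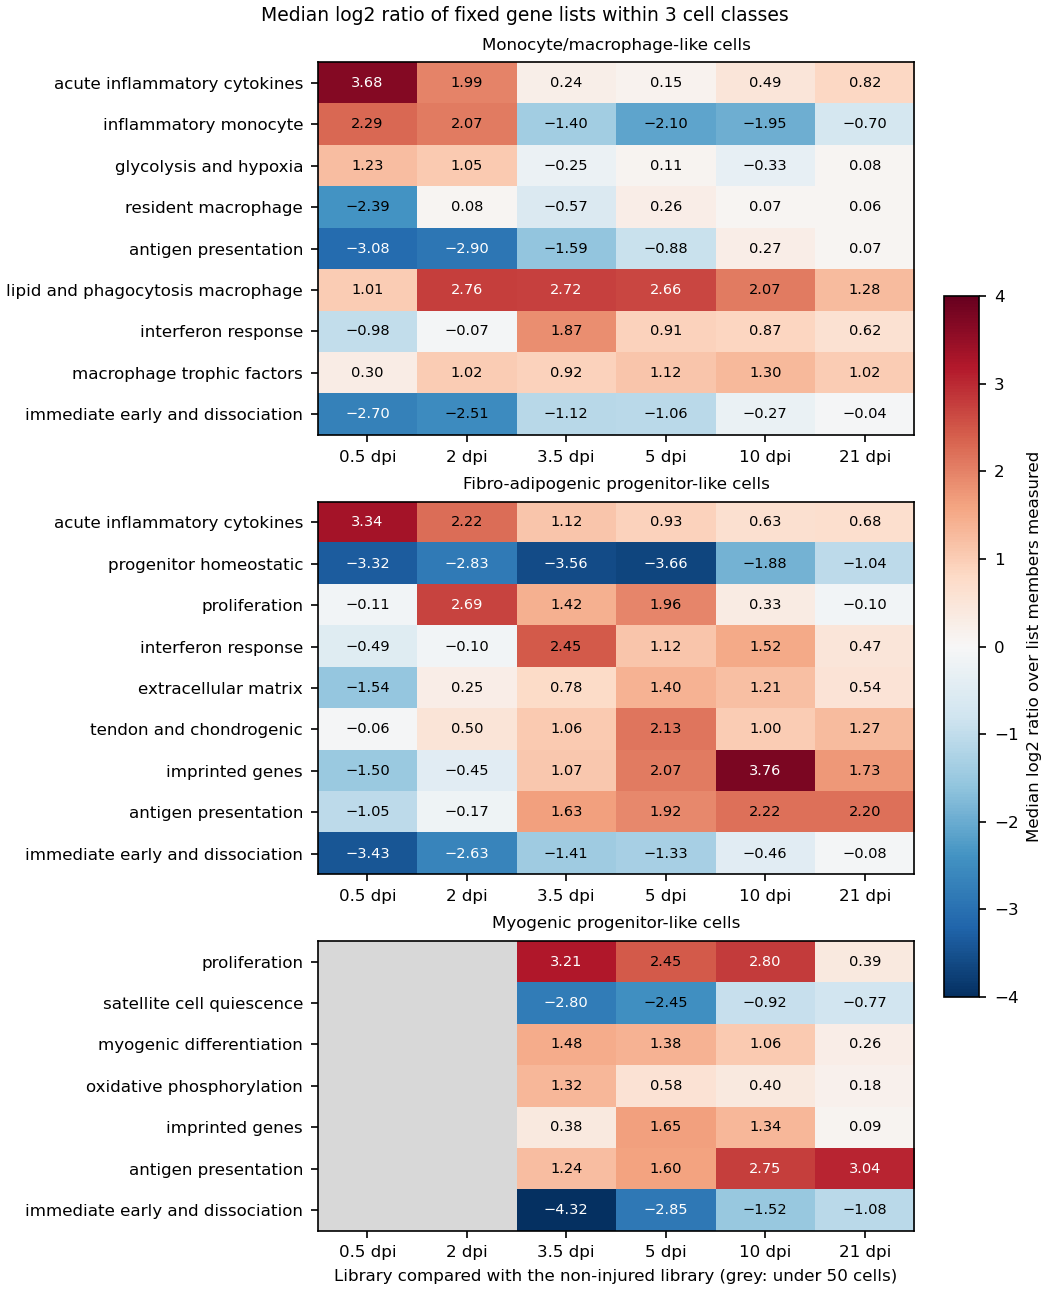
Median log2 ratio over the measured members of fixed gene lists (1 line per list) in 3 cell classes, for each injured library against the non-injured library, with colour from −4 to 4 and grey for fewer than 50 cells. In FAP-like cells the imprinted gene list is highest at 10 dpi (3.76) and the acute cytokine list at 0.5 dpi (3.34).

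The third comparison asks how FAP-like cells responded. At 0.5 dpi they had high values of chemokines and of single genes such as Tnc and Mmp3. Most of the extracellular matrix list and the genes typical of resting FAPs had low values. Cell cycle genes were higher at 2 dpi, interferon response genes at 3.5 dpi, collagen and other matrix genes at 5 dpi, and imprinted growth regulators at 10 dpi. At 21 dpi fewer genes differed from non-injured muscle than in any earlier library. Different clusters held the class over time: 14, 11 and 1 in non-injured muscle, 22 at 0.5 dpi (98.8%), 22 and 24 at 2 dpi (59.6 and 26.8%), 6 at 3.5 and 5 dpi, 8 at 10 dpi (80.6%), and 1 and 16 at 21 dpi. Cluster 24 was led by cell cycle genes and held 2 of the 3490 non-injured FAP-like cells.

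At 0.5 dpi, 833 genes were over 2-fold higher and 992 lower in FAP-like cells among 4032 genes, and the median of all measured genes was −0.31. All 15 acute inflammatory cytokine genes measured were over 2-fold higher, with a median 3.65 above that of all genes. Cxcl5, a neutrophil chemokine on chromosome 5 (90759360 to 90761624), stood at 20566 against 1.51 CPM, a log2 ratio of 10.80, and its value was 942% of that of the whole library. Ccl2, which recruits monocytes, stood at 9536 against 223.9, and Cxcl3 at 721.5 with the reference listed at 0. Tnc, the injury matrix protein tenascin C, stood at 1699.5 against 2.78, Mmp3, a matrix protease, at 3099 against 29.0, and Il1rl1, the receptor of IL-33, at 807.8 against 0.618. Of 12 homeostatic FAP genes, 5 of them also FAP markers, 11 were over 2-fold lower, with a median of −3.01 relative to all genes. Pi16, a marker of universal fibroblasts on chromosome 17 (29317680 to 29330593), stood at 20.7 against 1053 CPM. Extracellular matrix genes split, with 6 of 19 over 2-fold higher and 11 lower and a median of −1.23 relative to all genes (percentile 0.22), and Col1a2, a fibrillar collagen chain, stood at 391.8 against 4267. The immediate early and dissociation list lay at −3.12 and the adult myofibre list at −2.48 relative to all genes.

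At 2 dpi, 616 genes were over 2-fold higher and 558 lower in FAP-like cells (793 and 489 under median-ratio scaling), with the median of all genes at −0.22. Of 18 proliferation genes, 17 were over 2-fold higher, with a median 2.91 above all genes. Birc5, the mitotic regulator survivin on chromosome 11 (117849251 to 117855743), stood at 168.6 against 0.926 CPM and Mki67, encoding the proliferation antigen Ki-67, at 127.4 against 1.72. The acute cytokine list lay 2.44 above all genes and the homeostatic list at −2.61 relative to them. Timp1, a protease inhibitor, stood at 3233 against 38.7. At 3.5 dpi, 365 genes were higher and 430 lower (413 and 405 under median-ratio scaling). Interferon response genes had a median of 2.45, with 11 of 12 over 2-fold higher, such as Isg15, a ubiquitin-like modifier, at 256.2 against 13.9 and Cxcl10, a T cell chemokine, at 462.0 against 46.4. Homeostatic genes had a median of −3.56, with Gsn, encoding the actin-severing protein gelsolin, at 501.4 against 24711.

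At 5 dpi, 373 genes were over 2-fold higher and 435 lower in FAP-like cells (427 and 399 under median-ratio scaling). Of 19 extracellular matrix genes, 12 were over 2-fold higher and none over 2-fold lower, with a median of 1.40. Postn, encoding the matrix protein periostin on chromosome 3 (54361109 to 54391037), stood at 6066 against 16.2 CPM, a log2 ratio of 7.86. Tnc stood at 916.7 and Col12a1, a fibril-associated collagen, at 517.7 against 24.5. Acta2, the smooth muscle actin of contractile fibroblasts, stood at 938.2 against 3.50, and Ptn, a secreted growth factor, at 1394 against 10.3. All 8 tendon and chondrogenic genes measured were over 2-fold higher, with a median of 2.13 (1.34 to 3.28 over the alternatives), and 6 members of that list were also tenocyte markers. Thbs4, a tendon matrix protein, stood at 721.9 against 33.6. Homeostatic genes had a median of −3.66, with Hsd11b1, a glucocorticoid-activating enzyme, at 10.7 against 647.1. Imprinted genes, which are expressed from 1 parental copy and often regulate growth, had a median of 2.07.

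At 10 dpi, 184 genes were over 2-fold higher and 185 lower in FAP-like cells. Of 10 imprinted genes, 9 were over 2-fold higher, with a median of 3.76. Dlk1, a Notch ligand relative that restrains adipogenesis on chromosome 12 (109452823 to 109463336), stood at 2106 against 15.6 CPM, a log2 ratio of 6.37 and 255% of the whole-library value. H19, a growth-restraining long noncoding RNA on chromosome 7 (142575529 to 142578143), stood at 1062 against 10.4, and Igf2, a growth factor, at 945.0 against 28.6. Extracellular matrix genes had a median of 1.21 and interferon response genes 1.52. The antigen presentation list had a median of 2.22, but Cd74 stood at 275.2 against 44.3, which was 3.22% of its whole-library value. At 21 dpi, 91 genes were higher and 89 lower, or 196 and 42 under median-ratio scaling, and the median of all genes was −0.21. The imprinted list lay 1.94 above all genes, the antigen presentation list 2.40 above them, and the homeostatic list at −0.83 relative to them with 6 of 12 members over 2-fold lower. Not set against all genes, the antigen presentation median was 2.20, and 1.44 without shallow cells. Cd74 stood at 9.67% of its whole-library value, and macrophage markers in these cells at a median of 26.8% (4.76 to 59.8%). Dpp4, a peptidase of universal fibroblasts, stood at 39.7 against 169.4. Shallow cells, by the definition above, made up 35.0% of FAP-like cells at 21 dpi and 3.90% in non-injured muscle.

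**Figure D3:**
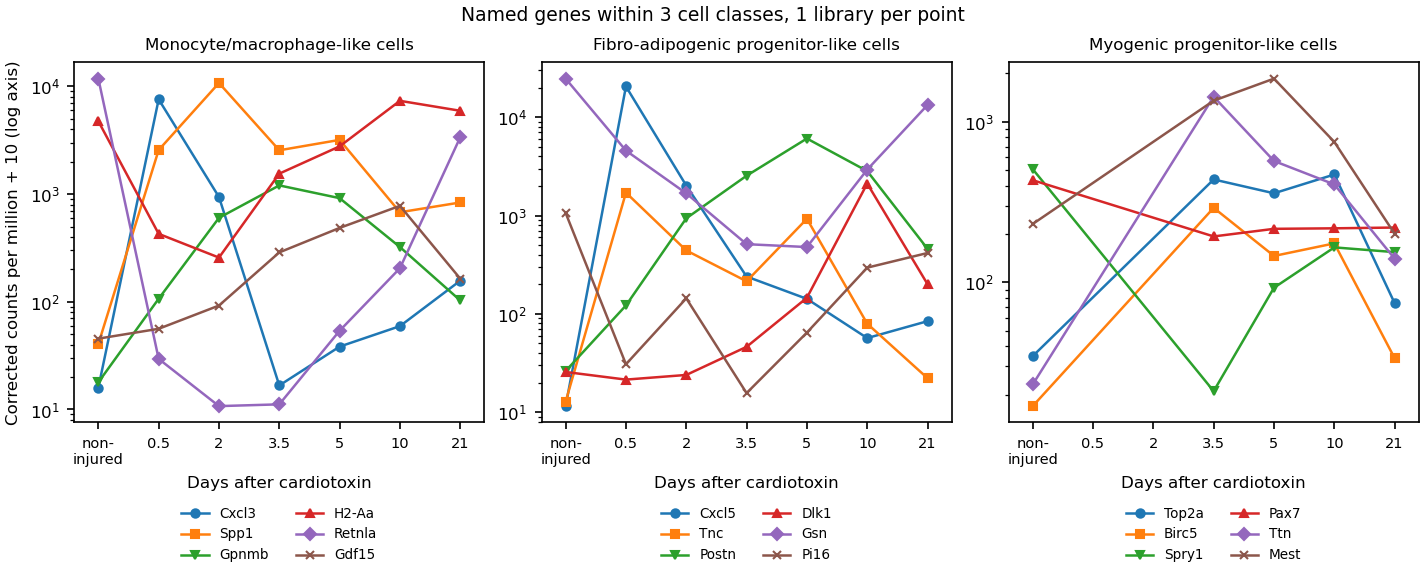
CPM of corrected counts plus 10 (y axis, log scale) of 6 named genes in each of 3 cell classes by days after cardiotoxin (x axis), with 1 library per point. Cxcl5 in FAP-like cells is highest at 0.5 dpi (20566), Postn at 5 dpi (6066) and Dlk1 at 10 dpi (2106).

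The fourth comparison asks how myogenic progenitor-like and myocyte-like cells differed from those of non-injured muscle. At 3.5 dpi myogenic progenitor-like cells had high values of cell cycle genes and low values of genes of quiescent stem cells. Cell cycle genes were still higher at 10 dpi, and at 21 dpi their difference from non-injured muscle depended on how cells were assigned to the class. Myocyte-like cells at 5 dpi had high values of genes of differentiation and fusion and low values of adult myofibre genes. With 8 and 23 progenitor-like cells at 0.5 and 2 dpi, under the minimum of 50, those time points were not compared.

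At 3.5 dpi, 897 genes were over 2-fold higher and 459 lower in myogenic progenitor-like cells, with a median of all genes of 0.22; under median-ratio scaling 582 were higher and 565 lower. Of 18 proliferation genes, 17 were over 2-fold higher, with a median 2.99 above all genes. Top2a, the mitotic topoisomerase, stood at 426.7 against 24.7 CPM, Birc5 at 280.8 against 6.94, and Rrm2, a subunit of ribonucleotide reductase, at 285.9 against 11.6. Of 12 satellite cell quiescence genes, 2 of which were class markers, 9 were over 2-fold lower, with a median of −3.02 relative to all genes. Spry1, an inhibitor of growth factor signalling on chromosome 3 (37639947 to 37644598), stood at 11.0 against 496.1, and Gas1, a growth arrest protein, at 84.7 against 1132. Chrdl2, a BMP antagonist, was listed at 0 against 153.5. Pax7, the stem cell transcription factor, stood at 182.9 against 422.0. Oxidative phosphorylation genes lay 1.09 above all genes (percentile 99.8), with 10 of 12 over 2-fold higher, such as Cox5a, a subunit of cytochrome c oxidase, at 920.8 against 243.8. Differentiation genes lay 1.26 above all genes, with Ttn, encoding the giant sarcomere protein titin, at 1420.4 against 13.1. The immediate early and dissociation list lay at −4.54 relative to all genes, with Fos, a digestion-induced transcription factor, at 243.8 against 8701.

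At 5 dpi, 578 genes were over 2-fold higher and 295 lower in myogenic progenitor-like cells (269 and 411 under median-ratio scaling), with a median of all genes of 0.34. Proliferation genes lay 2.12 above all genes and quiescence genes at −2.79 relative to them. Imprinted genes lay 1.31 above all genes, with Mest, a mesoderm-expressed hydrolase, at 1843 against 220.7 CPM, and Meg3, a long noncoding RNA, lower at 245.4 against 3075. At 10 dpi, 463 genes were higher and 173 lower (196 and 279 under median-ratio scaling), with a median of all genes of 0.36. All 18 proliferation genes measured were over 2-fold higher, with a median 2.44 above all genes, and Stmn1, a microtubule regulator, stood at 647.2 against 42.4. Quiescence genes lay at −1.29 relative to all genes. At 21 dpi, 275 genes were higher and 97 lower, and quiescence genes had a median of −0.77, with Spry1 at 144.1. Proliferation genes had a median of 0.39 (percentile 99.6), and 1.77 when each cell was given a class from its marker scores. At that time point 36.2% of the class lay in cluster 32.0, against 2.41% in non-injured muscle. Shallow cells made up 48.9% of the class at 21 dpi and 13.9% in non-injured muscle. Antigen presentation genes lay 2.39 above all genes at 10 dpi and had a median of 3.04 at 21 dpi, but Cd74 stood at 4.66% of its whole-library value at 10 dpi and at 18.0% at 21 dpi. Not set against all genes, the median at 10 dpi was 2.75, and 1.02 without the highest doublet scores, and at 21 dpi it was 0.72 under the stricter cell filter.

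Myocyte-like cells lay in cluster 12 in non-injured muscle (99.7%) and in cluster 31 at 5 dpi (98.1%). At 10 dpi 65.2% lay in cluster 12 and 33.3% in cluster 31, and at 21 dpi 86.0% lay in cluster 12, 10.3% in cluster 32.3 and 3.74% in cluster 31. The 5 dpi comparison cannot be made at resolution 0.5, where 1 myocyte-like cell was left. Myocyte-like cells had a median of 1378 genes detected and 0.212% mitochondrial counts in non-injured muscle, against 2870 and 4.84% at 5 dpi. The values below therefore compare unlike droplets and cannot be read as a change within a cell type. At 5 dpi, 1648 genes were over 2-fold higher and 597 lower, or 863 and 837 under median-ratio scaling, and the median of all genes was 0.84. Of 14 myogenic differentiation genes, 5 of them myocyte markers, 12 were over 2-fold higher and 1 lower, with a median 5.21 above all genes. Myog, the transcription factor of differentiating myocytes on chromosome 1 (134289989 to 134292548), stood at 6312 against 23.2 CPM. Cdkn1c, a cell cycle inhibitor on chromosome 7 (143458339 to 143461050), stood at 10854 against 40.4, and Tnnt2, the troponin of immature muscle, at 2448 against 2.56. Gm7325, the older symbol of the fusion peptide Mymx, stood at 944.3 against 0.107. All 12 adult myofibre genes were over 2-fold lower, with a median of −5.62 relative to all genes, such as Ckm, the muscle creatine kinase, at 426.4 against 24177. Imprinted genes lay 3.87 above all genes, with Peg3, a zinc finger protein, at 732.9 against 3.31. At 10 dpi, with a median of all genes of 0.37, differentiation genes lay 3.50 above all genes and adult myofibre genes at −1.19 relative to them (percentile 0.05). At 21 dpi differentiation genes had a median of 1.94, with Myog at 328.8. Shallow cells made up 70.1% of myocyte-like cells at 21 dpi and 30.1% in non-injured muscle.

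Progenitor-like and myocyte-like cells were also combined as myogenic cells. At 3.5 dpi, 1550 genes were over 2-fold higher and 587 lower (692 and 829 under median-ratio scaling), with Nes, an intermediate filament of activated stem cells, at 482.4 against 3.56 CPM and Mb, encoding the oxygen carrier myoglobin, at 3.61 against 3119.8. At 5 dpi the counts were 1732 and 585 (625 and 893 under median-ratio scaling), with Mest at 1599.6 against 27.8 and Pvalb, the calcium buffer of fast fibres, at 7.58 against 5024. At 10 dpi they were 1256 and 413 (542 and 692 under median-ratio scaling). These values combine the shift from myocyte-like to progenitor-like cells with differences inside each class.

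The fifth comparison asks how endothelial-like cells differed during regrowth. Non-injured muscle held 43 endothelial-like cells, under the minimum of 50, so 21 dpi (309 cells) served as the reference. Endothelial-like cells at 5 dpi had higher values of some vessel sprouting genes and slightly higher values of cell cycle genes than at 21 dpi. At 10 dpi the median of the cell cycle genes was again higher, though not every member was, and that of the sprouting genes was not.

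At 5 dpi (98 cells), 83 genes were over 2-fold higher and 183 lower in endothelial-like cells than at 21 dpi. The tip cell list had a median of 0.66, with 2 of 11 measured members over 2-fold higher and 1 lower. Plvap, which forms the diaphragms of fenestrated vessels on chromosome 8 (71497765 to 71511752), stood at 832.9 against 307.9 CPM, and Pgf, placental growth factor, at 181.3 against 70.5. Flt4, the lymphatic growth factor receptor, stood at 21.8 against 64.7. Col18a1, the precursor of endostatin, stood at 440.3 against 93.2, and Chga, a secretory granule protein, at 220.8 against 9.95. Ccl21a, a chemokine of lymphatic vessels, was listed at 0 against 1778. Ccl21a was detected in 23 of the 309 cells at 21 dpi (7.44%, 4.78 to 10.96%), and Chga in 11 of 98 cells at 5 dpi (11.2%, 5.74 to 19.2%). Endothelial activation genes had a median of 0.19 at percentile 86.0, and the median ranged from −0.17 to 0.29 over the alternatives. Proliferation genes had a median of 0.62, with 4 of 16 over 2-fold higher. The adult myofibre list, read here as free RNA, had a median of −3.48, with Acta1 at 21 dpi at 21.5% of its whole-library value. The genes of resting FAPs had a median of −1.90, with 8 of 10 over 2-fold lower, and Dcn, a FAP marker, stood at 81.8 against 1120. FAP markers stood at a median of 11.3% of their whole-library value at 5 dpi and 10.7% at 21 dpi. The immediate early and dissociation list had a median of −0.87. The 183 lower genes thus include genes of other cells and genes that respond to digestion, and the cause of the latter was not tested. Among the 83 higher genes were macrophage genes, with C1qa, a complement subunit, at 309.5 against 126.6 and Lyz2, a lysozyme, at 1291 against 496.5. At 10 dpi (121 cells), 35 genes were higher and 57 lower (22 and 64 under median-ratio scaling). The tip cell list had a median of −0.12 at percentile 11.2, with alternatives from −0.19 to 0.02, and proliferation genes had a median of 0.91, with 7 of 16 over 2-fold higher. Nts, encoding the peptide neurotensin, stood at 166.7 against 34.8 at 10 dpi.

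The sixth comparison asks which cells carried proliferation transcripts, counted as cells with at least 2 corrected counts over the list after thinning each cell to 2000 counts. Myogenic progenitor-like cells at 3.5 dpi and FAP-like cells at 2 dpi had the highest shares among the 3 classes of this paragraph. In myogenic progenitor-like cells the share was 6.63% in non-injured muscle (11 of 166 cells, 3.35 to 11.5%), 77.4% at 3.5 dpi (260 of 336, 72.5 to 81.7%), 40.1% at 5 dpi, 38.5% at 10 dpi and 7.09% at 21 dpi. Among FAP-like cells it was 1.09% in non-injured muscle, 4.45% at 0.5 dpi, 46.5% at 2 dpi (212 of 456, 41.8 to 51.2%), 21.8% at 3.5 dpi, 25.2% at 5 dpi, 2.28% at 10 dpi and 1.54% at 21 dpi. In monocyte/macrophage-like cells it was 11.6% in non-injured muscle (6.66 to 18.5%), 5.77% at 0.5 dpi and 18.8% at 5 dpi (17.7 to 19.9%). Neutrophil-like cells, which do not divide once mature, gave the background, with 6.78% at 2 dpi, 9.21% at 3.5 dpi and 6.06% at 5 dpi. FAP markers in these cells stood at medians of 104%, 105% and 70.8% of their whole-library values, so this background includes RNA of other cells. Median genes detected were 2799.5 in FAP-like cells at 2 dpi, 2870 in progenitor-like cells at 3.5 dpi and 2308 in monocyte/macrophage-like cells at 5 dpi, against 1444, 1568.5 and 1537.5 in neutrophil-like cells of the same libraries. Without thinning the shares were 68.0%, 97.6% and 58.3% in those 3 classes, and 26.5%, 27.6% and 19.7% in the neutrophil-like cells.

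**Figure D4:**
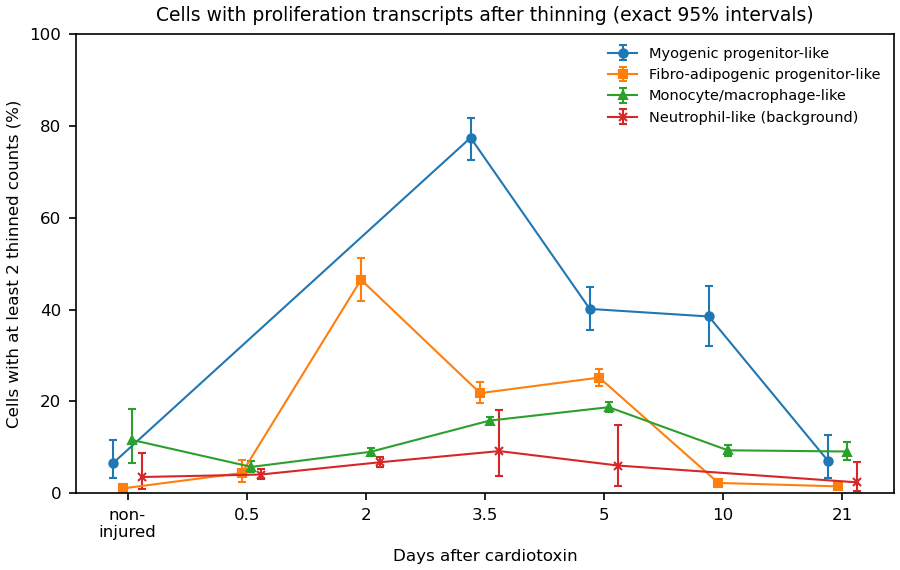
Share of cells with at least 2 thinned counts over the proliferation list (y axis, percent, exact 95% intervals) by days after cardiotoxin (x axis) in 4 cell classes, with neutrophil-like cells as background. Myogenic progenitor-like cells reach 77.4% at 3.5 dpi and FAP-like cells 46.5% at 2 dpi.

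Whole libraries were compared as well, which mixes the change in cell classes with differences inside them. At 0.5 dpi, 981 genes were over 2-fold higher and 1143 lower than in non-injured muscle. At 2 dpi the counts were 890 and 914, at 3.5 dpi 695 and 870, at 5 dpi 618 and 671, at 10 dpi 459 and 440, and at 21 dpi 201 and 266. Under median-ratio scaling they were 809 and 796 at 3.5 dpi, 663 and 643 at 5 dpi and 239 and 228 at 21 dpi.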

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

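The tests of free RNA, doublets, shallow cells, neighbouring libraries and cell handling in this part were chosen after the results were seen. Medians in this part are not set against all genes.

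In monocyte/macrophage-like cells the inflammatory monocyte list had a median log2 ratio of 2.29 at 0.5 dpi and −2.10 at 5 dpi, so the libraries differed from non-injured muscle in opposite directions. In FAP-like cells the extracellular matrix list had a median of 1.40 at 5 dpi and −1.54 at 0.5 dpi. Neither difference was tested, since each time point is 1 library. Outside the named classes, an unnamed cluster (19.1) held 1.21% of the cells at 5 dpi (115 cells, 1.00 to 1.45%) and 0.471% at 3.5 dpi (53 cells), against 0.0353% in non-injured muscle (2 cells, 0.00427 to 0.127%). This difference was not tested either. The genes that led this cluster included Acp5, Ctsk, Mmp9 and Nfatc1, which are used by osteoclasts and other macrophage-lineage cells. The cluster stayed unnamed because its leading genes held more markers of another class than of its best-scoring class, monocyte/macrophage. No osteoclast markers were fixed beforehand, and whether bone was taken with the muscle is not given in the sources used here.

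Antigen presentation genes were higher in FAP-like and myogenic progenitor-like cells at 10 dpi than in non-injured muscle, with medians of 2.22 and 2.75. RNA of macrophage-like and dendritic-like cells in the droplets may account for much of this. In FAP-like cells the measured members stood at a median of 3.51% of their whole-library value, inside the range of macrophage markers in the same cells (2.81 to 4.52%). In myogenic progenitor-like cells they stood at 5.60%, inside 2.83 to 7.62%. Removing the highest doublet scores left a median of 1.54 in FAP-like cells and 1.02 in myogenic progenitor-like cells, and such removal does not take out every doublet, so a part from doublets stays open.

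Imprinted genes were higher in FAP-like cells at 10 dpi, with a median of 3.76. Free RNA from another class is argued against, since the members stood at a median of 233% of their whole-library value, while macrophage markers in these cells stood at 3.50%. The median log2 ratio was 3.77 without shallow cells, which made up 5.04% of FAP-like cells at 10 dpi and 3.90% in non-injured muscle. With so few shallow cells, this removal could move the median little. The neighbouring libraries had medians of 2.07 at 5 dpi and 1.73 at 21 dpi (1.17 to 2.00 over the alternatives). The direction was therefore not limited to the 10 dpi library. At 21 dpi, however, shallow cells made up 35.0% of the class, and 25.8% of it lay in cluster 16. That cluster was led by genes such as Dlk1, Igf2 and Meg3, and 1424 of its 1543 cells came from the 21 dpi library. All these medians share the non-injured reference, and the higher value at 10 dpi is not accounted for. A stage of regeneration in which FAPs express growth-regulating genes such as Dlk1, Igf2 and H19 may account for the values. This is a hypothesis found and examined on the same data, with 1 library per time point.

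Immediate early and dissociation genes were lower at 0.5 dpi than in non-injured muscle in each of the 4 classes measured, with medians from −3.43 in FAP-like cells to −0.75 in neutrophil-like cells. A difference in cell handling between the 2 libraries could lower such genes in every class. So could a response of the cells to injury, and with 1 library per time point these cannot be told apart.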

How the results depend on the processing

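Removing shallow cells, median-ratio scaling and putting unnamed clusters in their best class were chosen after seeing the data, as were the stricter cell filter and a class per cell for list medians and the stricter filter for single genes.

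Of the list medians recomputed under the alternatives, 496 stayed within 1.5-fold of the main value, 56 kept their sign but moved further and 1 reversed from a main value of at least 1 on the log2 scale. For single named genes these counts were 2469, 372 and 1. Among those that stayed within 1.5-fold, 3 list medians and 3 gene ratios near 0 changed sign, each in endothelial-like cells; the endothelial activation list at 5 dpi went from 0.19 to −0.17 with a class per cell and to −0.078 without shallow cells, and the tip cell list at 10 dpi from −0.12 to 0.023 with a class per cell. Gene counts stayed within 1.5-fold of the main count in 321 comparisons and moved further in 55. Class shares stayed inside the main 95% interval in 480 comparisons and left it in 157, and proliferation shares stayed in 117 and left it in 85. The other Leiden resolutions and the assignment of unnamed clusters were applied to class shares only. Whether the other values hold at another Leiden resolution was therefore not tested. The mean over cells left all 79 list medians, 406 gene ratios and 48 gene counts within 1.5-fold. With corrected totals of 5509 to 9930 per cell, that alternative could move values little.

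The share of neutrophil-like cells at 0.5 dpi was 36.4% under the stricter cell filter, 39.7% with a class per cell, 37.4% with unnamed clusters assigned and 14.7% without shallow cells, since 68.8% of the class was shallow. The share of monocyte/macrophage-like cells at 3.5 dpi was 69.2% at Leiden resolution 0.5, 61.5% with a class per cell, 68.9% without shallow cells and 70.9% with unnamed clusters assigned. The share of myocyte-like cells in non-injured muscle was 24.6% with a class per cell, 18.0% without shallow cells and 24.1% with unnamed clusters assigned. The share of FAP-like cells at 21 dpi was 58.1% with a class per cell and 65.4% without shallow cells. The dendritic-like share at 3.5 dpi was 9.83% with a class per cell, and the myogenic progenitor-like share at 5 dpi was 5.66% at resolution 0.5. Except for the neutrophil-like share without shallow cells, the cause was not tested.

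A minimum of 10 CPM considers more genes, and the number over 2-fold was then 1889 in monocyte/macrophage-like, 3107 in FAP-like and 3785 in all cells at 0.5 dpi, 2258 in myogenic progenitor-like cells at 3.5 dpi, 4580 in myogenic cells at 5 dpi and 567 in endothelial-like cells at 5 dpi. Median-ratio scaling gave 1518 in myogenic cells at 5 dpi; the cause was not tested.

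Adding 1 in place of 10 CPM widens the ratios of genes with low values. List medians, not set against all genes, were then 4.56 for acute cytokines in monocyte/macrophage-like cells and 4.04 in FAP-like cells at 0.5 dpi, 4.60 for proliferation in FAP-like cells at 2 dpi, 3.10 for interferon response in FAP-like cells at 3.5 dpi, 3.87 for proliferation and −3.49 for quiescence in myogenic progenitor-like cells at 3.5 dpi, and 7.42 for differentiation in myocyte-like cells at 5 dpi. Antigen presentation in monocyte/macrophage-like cells at 0.5 dpi had a median of −2.09 under the stricter cell filter; the cause was not tested.

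The 2 reversals were in neutrophil-like and monocyte/macrophage-like cells. The interferon response list in neutrophil-like cells at 2 dpi was at 0.17 without shallow cells against −1.34. That value rests on few reference cells, since 99 of the 112 neutrophil-like cells in non-injured muscle were shallow. H2-DMb2 in monocyte/macrophage-like cells at 10 dpi was at 0.074 under the stricter filter against −1.78. The cause of these reversals was not tested.

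Thinning to 1000 and a minimum of 3 counts leave fewer counts or ask for more, and gave proliferation shares of 62.8% and 69.3% in myogenic progenitor-like cells at 3.5 dpi, 32.9% and 37.7% in FAP-like cells at 2 dpi, and 9.24% and 9.85% in monocyte/macrophage-like cells at 5 dpi.

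The alternative with no cell filter kept the same cells, because the main filter removed 0. Scaling factors that need counts were not run on corrected counts, and median-ratio scaling was used in their place. The depth of each cell is unknown, so no precision was given for a gene value.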

Other observations

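Classes outside the main comparisons gave these values, and the lists described here were chosen after their medians were seen. Neutrophil-like cells at 0.5 dpi had a median log2 ratio of 2.40 for the acute cytokine list, with 11 of 14 members over 2-fold higher. Cxcl3 stood at 1874 against 5.32 CPM, Ccl4, a chemokine for monocytes and T cells, at 6882 against 163.5, and Tnf, the tumour necrosis factor, at 2837 against 135.6. Il1a, an alarm cytokine, was at 828.7 and listed at 0 in non-injured muscle. The adult myofibre list, read as free RNA, had a median of −3.57 in the same cells. Ccl4 stood at 267% of its whole-library value, Tnf at 203% and Cxcl3 at 41.5%. FAP markers, read as free RNA, stood at a median of 37.1% in these cells (4.47 to 145%) and at 3.19% in non-injured muscle, so the Cxcl3 value lies in their range. Col1a1, a FAP marker, was nevertheless lower, at 119.6 against 232.7 CPM. At 2 dpi the interferon response list had a median of −1.34, with 8 of 12 members lower, such as Isg15 at 141.7 against 788.4. The sign reversed without shallow cells. Shallow cells made up 99 of the 112 neutrophil-like cells in non-injured muscle and 1863 of the 1975 at 2 dpi. Their removal thus left few reference cells, so the reversal cannot decide the direction, which stays open. FAP markers stood at a median of 104% of their whole-library value at 2 dpi (18.6 to 245%), with Col1a1 at 236.7 CPM. At 2 dpi 82.9% of the class lay in cluster 10, whereas 93.8% of the 112 cells in non-injured muscle lay in cluster 15.

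Dendritic-like cells at 0.5 dpi had a median of 2.15 for inflammatory monocyte genes, with Vcan at 354.7 against 8.32 CPM. At 3.5 dpi the interferon response list had a median of 1.13 and the lipid and phagocytosis list 1.99 (1.25 to 3.25 over the alternatives). Fabp5 stood at 684.4 against 14.6, which was 32.7% of its whole-library value. The reference held 60 dendritic-like cells. Tenocyte-like cells at 10 dpi had a median of 1.88 for imprinted genes, with 8 of 10 over 2-fold higher, and Mest stood at 1933 against 82.9. At 5 dpi, with 66 cells, interferon response genes had a median of 2.19 in tenocyte-like cells, and Irf7, an interferon-induced transcription factor, stood at 82.4 against 2.73. In the same comparison antigen presentation genes had a median of 2.72, with 6 of 6 over 2-fold higher, resident macrophage genes 1.55 and lipid and phagocytosis genes 1.03. Macrophage markers in these cells stood at a median of 8.69% of their whole-library value (0 to 24.4%), against 39.5% for Irf7, so a part of the interferon values from macrophage RNA stays open.

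T cell-like cells numbered 57 at 10 dpi and 76 in non-injured muscle, and lay mainly in cluster 25.2 (87.7%) and in cluster 25.0 (100%) respectively. Cluster 25.0 was led by genes such as Csf2, Gata3 and Il5, and cluster 25.2 by genes such as Nkg7, Gzma and Cd8b1. The T cell marker score was 0.943 in cluster 25.0, with 3 markers detected, and 4.15 in cluster 25.2, with 5 detected. The T cell name is thus weak for the reference cells, and whether they are T cells stays open. The values below therefore compare different clusters and cannot be read as a change within a cell type. With a median of all genes of 0.46, the lymphocyte cytotoxicity list lay 4.20 above all genes, with 6 of 7 over 2-fold higher, and 2 of its members were also NK cell markers. Ccl5, a chemokine of effector T cells, stood at 4289 against 57.2 CPM and Nkg7, a granule protein, at 2521 against 50.1. Gzmk, a granzyme, was at 289.2 and Ifng, interferon gamma, at 242.1, both listed at 0 in non-injured muscle. The proliferation list lay 4.02 above all genes, with 18 of 18 over 2-fold higher and 7 members listed at 0 in the reference. When each cell was given a class from its marker scores, the cytotoxicity median, not set against all genes, was 2.31 in place of 4.66 and the proliferation median 1.75 in place of 4.48. At Leiden resolution 2.0, cluster 42, whose leading genes include Nkg7 and which held 61 cells of the 10 dpi library, stayed unnamed. The share of T cell-like cells with proliferation transcripts was 89.5% at 10 dpi (51 of 57, 78.5 to 96.0%) and 2.63% in non-injured muscle (2 of 76), with 96.5% and 34.2% before thinning. Median genes detected were 2868 and 1574, and the neutrophil-like class at 10 dpi, with 26 cells, was too small to give a background.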
